A study of Danio rerio with 26 samples.

How the data were processed

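Total RNA from the skin of 26 male zebrafish was sequenced, with 1 library per fish, prepared with the TruSeq RNA Library Preparation Kit v2 per the labels. Per the submitters' processing notes, CASAVA 1.8.2, STAR 2.4.1d and featureCounts 1.4.6-p4 were used with the GRCz10 genome build. The role of each tool, the read length, the duration of the rotenone treatment and the hour of sampling are not given in the sources used here. The authors deposited counts per Ensembl gene (whole numbers, no normalization) for 32105 genes and values named RPKM, each in a table for the 17 fish at 37.5 nM and in a further table for the 9 fish at 3.75 nM. No replicates were pooled. The deposited RPKM values were not scaled by each library's own total. In genes with at least 300 counts, the ratio of count to RPKM, taken between 2 libraries, repeated every 50 genes down the table. Residual variance was 3.2e-05% at 37.5 nM and 1 year, and the log2 ratio ranged from -0.509 to 0.391. The RPKM values therefore entered only as an alternative.

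Groups were taken from the age and perturbation labels. The 3-year fish (n = 8) were compared with the 1-year fish (n = 9) at 37.5 nM, and the 1-year fish at 37.5 nM (n = 9) with those at 3.75 nM (n = 9). The fish numbers in the titles formed a low and a high run in every group (4 and 5, 4 and 4, and 4 and 5 fish), used only as a batch. Replicate numbers follow the order of deposition and carry no pairing. Comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

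Counts were normalized by TMM, filtered with filterByExpr and tested with edgeR 4.0.16 (robust glmQLFit and glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The p-values measure the spread between fish. The standard error of a log2 fold change was taken as its size over the square root of F. Total counts per fish ranged from 25454674 to 35162246. The biological coefficient of variation was 0.396 between ages and 0.400 between concentrations. The procedure was tested on simulated data of the same size with 200 changed genes, picked above a minimum mean CPM. A further list of genes, shifted as a whole, was not counted among the false calls. The procedure recovered 67% of 2-fold and 94% of 4-fold changes between ages and 74% and 99% between concentrations. False calls made up 5.03% and 3.68% of calls, and data without change gave 0 calls between ages and 1 between concentrations. The simulated genes were drawn independently, without number-run or muscle differences, so these rates need not carry over to the real data.

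The 29 gene lists covered complex I, respiratory complexes II to V, mitochondrial-genome genes, antioxidant and Nrf2 targets, the integrated stress and mitochondrial unfolded protein response, glycolysis, heat shock, cell cycle, p53 targets and senescence, inflammatory cytokines, interferon response, complement, the circadian clock, lipid synthesis, the proteasome and cytosolic ribosomal proteins. Cell type lists covered keratinocytes, dermal fibroblasts, scale bone cells, melanophores, xanthophores and iridophores, skeletal muscle, endothelial cells, erythrocytes, lymphocytes, macrophages, neutrophils, mucous cells and ionocytes, and Schwann cells and nerve. Symbols are those of the annotation used here. The complex I list holds ndufa4 genes, whose product is now assigned to complex IV, and the list of complexes II to V holds cytochrome c. Of the list identifiers, 813 were matched by the written symbol and 143 by its stem, and 107 entries had no identifier. Of all identifiers, 4144 share a symbol, and such genes are given with their identifier. Lists were tested with limma 3.58.1 camera (preset correlation 0.01, log2 CPM with a prior count of 2), adjusted over the 29 lists, with an estimated correlation and with fry as alternatives. Camera compares a list with the other genes, while fry compares it with no change. Fry's calls are those of its test for a shared direction, unless its test of change in either direction is named.

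Named genes were those past the threshold with an average log2 CPM of 2 or more, a symbol that is not a placeholder and the called direction in 80% or more of the pairs of fish, taking the 8 largest changes in each direction. To these were added 3 members of each called list, 1 member of an uncalled list where it passed adjusted over the list alone, and 13 genes named in advance, of which gstp1 had no identifier under that symbol. The BMAL1 values in both comparisons, the dbpa and nfil3-5 values between concentrations and actc1b were chosen after their values were seen. List means per fish were compared by exact permutation of the fish, two-sided, adjusted over 42 comparisons, and related to the mean of the muscle list by permutation tests over 6 relations. With the muscle mean as a term, the group labels were permuted over the residuals of the fit on that mean.

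Alternatives fixed in advance were RLE size factors, library size alone, no count filter, at least 10 counts in 8 fish, DESeq2 1.42.0, limma-trend on log2 RPKM with 0.1 or 1 added (mean RPKM of 0.5 or more), all 26 fish in 1 fit, number run as a term, each number run alone, glmTreat against a fold change of 1.5 and each fish left out. Chosen after seeing the data were a term for the muscle list mean, leaving out fish whose muscle list mean lay over 1 log2 unit above the mean of all fish, and list tests within each number run. Genomic positions, isoforms, sequence variants and raw reads were not analysed here.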

Results

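The skin of 26 male zebrafish was profiled by RNA sequencing, with 1 library per fish. All fish had received rotenone, an inhibitor of mitochondrial complex I. There were 9 fish aged 1 year at 3.75 nM, 9 fish aged 1 year at 37.5 nM and 8 fish aged 3 years at 37.5 nM. Assigned counts per fish ranged from 25968091 to 32414459 at 1 year and 37.5 nM, from 25454674 to 35162246 at 3 years, and from 26161555 to 28481706 at 1 year and 3.75 nM. There were no untreated fish, so no value is an effect of rotenone against a baseline. The fish numbers in each group fell into a low run (12 fish in all) and a high run (14 fish in all), which the labels do not explain. The first 3 principal components of the log2 CPM (counts scaled by library size) held 15.4%, 13.6% and 11.7% of the variance.

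The comparison of 3-year with 1-year fish, both at 37.5 nM, asks how the skin transcriptome differs with age under 1 rotenone concentration. Among the called genes, fut9b.2 and fut9b.3 were close to off at 1 year, while IPO8 and muc5.1 were expressed at both ages and lower at 3 years. fut9b.2 (ENSDARG00000058299), a fucosyltransferase gene copy, averaged 23.0 ± 13.1 CPM (SD, n = 8) at 3 years and 0.130 ± 0.083 CPM (n = 9) at 1 year, a log2 fold change of 7.42 ± 0.53 (SE). Its neighbour in the gene family, fut9b.3 (ENSDARG00000027699), rose by 4.66 ± 0.33 on the log2 scale. IPO8 (ENSDARG00000058159), a nuclear import receptor, fell from 112 ± 7.93 CPM to 27.5 ± 18.8 CPM, by 2.02 ± 0.29 on the log2 scale. The mucin gene muc5.1 (ENSDARG00000070331), which encodes a gel-forming mucus protein, fell from 108.5 ± 30.4 CPM to 28.4 ± 22.0 CPM, by 1.93 ± 0.39 on the log2 scale.

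Of 18935 genes tested with edgeR's quasi-likelihood test, 241 changed at a Benjamini-Hochberg adjusted p under 0.05, 128 of them higher and 113 lower at 3 years. Of these, 78 rose and 65 fell by more than 2-fold. The other genes with the largest gains were AHSA1 (ENSDARG00000028664), a co-chaperone of Hsp90, at 4.86 ± 0.75 (log2 fold change ± SE, n = 8 and 9), CYP8B1 (ENSDARG00000053068), a cytochrome P450, at 3.19 ± 0.69, and smtnl1 at 2.02 ± 0.47. LMF2 (ENSDARG00000025859) followed at 1.93 ± 0.30, with the replication helicase genes MCM5 at 1.94 ± 0.43 and MCM2 at 1.91 ± 0.42. The AHSA1 copy averaged 10.3 ± 15.7 CPM (SD) at 3 years, a spread larger than its mean, against 0.354 ± 0.118 CPM at 1 year. Single 3-year fish moved 4 of these genes by over 1.5-fold: AHSA1 was 3.82 and smtnl1 1.3 without replicate 3, CYP8B1 2.50 without replicate 1 and nme2a -3.39 without replicate 6 (adjusted p = 0.00229, 0.0473, 0.0452 and 0.000472). The largest losses were adgrf3b at -2.54 ± 0.53, CYP1A1, a detoxifying cytochrome P450, at -2.50 ± 0.59, and nme2a at -2.46 ± 0.57. They were followed by MVK, the mevalonate kinase of sterol synthesis, at -1.72 ± 0.39, CD180, a Toll-like receptor homologue, at -1.60 ± 0.25, and lnc.85 at -1.55 ± 0.33. Low nme2a values also occurred in 1-year fish at 3.75 nM, with log2 CPM of -0.12, -0.84, -1.09 and -0.13 in replicates 1, 3, 8 and 9. The adjusted p of these 16 genes lay between 2.95e-07 and 0.0448, and each moved in its direction in 81.9% or more of the pairs of fish.

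Age and strain label went together in all fish, since only the 3-year fish carried the transgene Tg(flk:mCherry), so no gene can be assigned to age rather than strain. Within the low number run (4 against 4 fish) edgeR called 34 genes and within the high run (4 against 5) 19 genes. Of 31 genes called in the low run and measured in both, 90.32% had the same direction in the high run, with a median of 1.3 on the log2 scale there against 3.44 in the low run. Picking genes by the low run favours a larger value there. The 241 genes, called from both runs together, had medians of 1.14 and 1.18 in their direction in the low and high run. For a difference between runs edgeR called 0 genes (3138 at an unadjusted p under 0.05). Leaving out 1 fish moved the count of 241 to between 64 (without replicate 8 of the 1-year fish) and 712 (without replicate 6 of the 3-year fish). For fut9b.2 the within-run values were 7.28 and 7.55, for IPO8 -2.1 and -1.94, and for muc5.1 -2.49 and -1.55. CYP1A1 differed by -0.20 in the low run and by -3.17 in the high run, and the difference between runs had an adjusted p of 0.0733 in edgeR.

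Transcripts of the respiratory chain, the cell cycle and the heat shock response lay higher in the 3-year fish as lists by camera with its preset correlation, but no age list was called with an estimated correlation or by fry. All 40 measured genes of the list for complex I, the target of rotenone, had positive fold changes, with a median of 0.63, but 1 passed over all genes and 1 adjusted over the list alone. That gene was ndufa4b, a relative of a gene now assigned to complex IV rather than complex I, at 2.53 ± 0.57 (1.47 without replicate 3 of the 3-year fish, adjusted p = 0.0260) and 1.91 ± 2.86 CPM (SD) against 0.326 ± 0.156 CPM. NDUFV2 had 0.74 ± 0.25 and an edgeR adjusted p of 0.130. The list was called by camera (adjusted p = 1.67e-08, and adjusted p = 0.801 with an estimated correlation). Of 45 measured genes of the list for complexes II to V, 0 passed over all genes and 0 adjusted over the list alone, with a median of 0.55. At an unadjusted p under 0.05, edgeR passed 3855 of all genes. Among those genes, uqcrc2a had 0.88 ± 0.31 and COX7A2 0.46 ± 0.15. That list was called as well (adjusted p = 1.07e-06, and adjusted p = 0.801 with an estimated correlation). Its mean differed by 0.378 (exact permutation p = 0.0741), by 0.170 without replicate 3 of the 3-year fish (exact permutation p = 0.180) and by 0.188 without fish high in muscle (exact permutation p = 0.138). Within the low and the high run the median of the complex I list was 0.85 and 0.29, and that of complexes II to V 0.79 and 0.24.

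Skeletal muscle transcripts moved with these lists from fish to fish. The mean of the complex I list followed the mean of the muscle list across 26 fish with group means removed (Pearson's r = 0.706, permutation p = 1e-05, the smallest that the permutations can give, adjusted p = 1.5e-05 over 6 relations). Spearman's rho was 0.728 (permutation p = 3e-05), and r was 0.611 without the 2 fish farthest from the median. Within the low run r was 0.639 (permutation p = 0.0176) and rho 0.524 (permutation p = 0.0861), and r without 2 fish was 0.321, so the relation there rests on those fish. Within the high run r was 0.929 (permutation p = 1e-05), rho was 0.934, and r without 2 fish was 0.844. Replicate 3 of the 3-year fish held 17758 CPM of the muscle actin actc1b, against a median of 2095 CPM in the other 3-year fish. Without that fish the age difference of the complex I mean went from 0.445 to 0.221 on the log2 scale. The exact permutation p went from 0.0359 (0.116 adjusted over 42 comparisons of list means) to 0.0893.

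Of 42 measured cell cycle genes, 4 rose over all genes and 13 adjusted over the list alone, with 0 down and a median of 0.58 (camera adjusted p = 1.67e-08, and adjusted p = 0.801 with an estimated correlation). MCM6 (ENSDARG00000057683) rose by 1.56 ± 0.35 beside MCM2 and MCM5, all parts of the replicative helicase, while PCNA, the sliding clamp of DNA replication, had 0.89 ± 0.25 (edgeR adjusted p = 0.0807) and mki67, the proliferation marker, 0.31 ± 0.34. The list's median was 0.94 in the low run and 0.55 in the high run. Of 26 heat shock genes, 2 rose over all genes and 3 adjusted over the list alone, with a median of 0.36 (camera adjusted p = 0.0189, and adjusted p = 0.801 with an estimated correlation). Besides AHSA1 (ENSDARG00000028664) these were hsp70l, the inducible Hsp70, at 1.33 ± 0.28, and hsp90aa1.1, at 1.83 ± 0.49, which passed over the list alone. Levels of hsp70l were low at both ages, 1.42 ± 0.53 CPM (SD) at 3 years and 0.567 ± 0.231 CPM at 1 year. The heat shock list mean differed by 0.397 (exact permutation p = 0.0201, 0.116 adjusted over 42 comparisons of list means), by 0.310 with the muscle list mean as a term (permutation p = 0.0175) and by 0.276 without fish high in muscle (exact permutation p = 0.0663). The heat shock median was 0.49 in the low run and -0.01 in the high run, and the list was not called without replicate 2 or replicate 4 of the 3-year fish (highest adjusted p = 0.0674).

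Of 28 skeletal muscle genes, 0 passed over all genes and 1 rose adjusted over the list alone, with a median of 0.88 (camera adjusted p = 0.0236, and adjusted p = 0.967 with an estimated correlation). An ACTA1 copy (ENSDARG00000055618) had 3.84 ± 0.97, myhz2 had 2.60 ± 0.80 and a further ACTA1 copy (ENSDARG00000036371) 2.41 ± 0.82. Each moved by over 1.5-fold without 1 of the 3-year fish: the ACTA1 copies to 3.08 and 1.08 without replicate 2, and myhz2 to 1.76 without replicate 3. The muscle median was 2.1 in the low run and -0.60 in the high run, so its direction did not hold within runs. Of 39 proteasome genes, 0 passed over all genes and 1 rose adjusted over the list alone, with a median of 0.18 (camera adjusted p = 9.40e-04, and adjusted p = 0.967 with an estimated correlation). The proteasome subunit gene PSMB7 had 0.62 ± 0.16, PSMB4 0.26 ± 0.12 and PSMA6 (ENSDARG00000013966) 0.25 ± 0.12. The proteasome median was 0.03 in the low run and 0.33 in the high run, where camera's directions were opposite, and the list was not called without replicate 5 of the 3-year fish (adjusted p = 0.104).

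Genes of mucous cells, lipid synthesis, the circadian clock and lymphocytes lay lower in the 3-year fish as lists. Each of these lists lost its call with an estimated correlation (adjusted p = 0.801 with an estimated correlation for all 4). Of 21 mucous cell and ionocyte genes, 1 fell over all genes and 5 adjusted over the list alone, with a median of -0.29 (camera adjusted p = 0.00141). Beside muc5.1, foxa3, a transcription factor of mucous cells, had -0.59 ± 0.17 and the lectin ITLN1 -1.30 ± 0.38. Of 38 lipid synthesis and adipocyte genes, 1 fell over all genes and 1 adjusted over the list alone, with a median of -0.29 (camera adjusted p = 8.39e-04). That gene was insig1, a sterol sensor that restrains SREBP processing, at -1.21 ± 0.29, while the desaturase SCD had -1.18 ± 0.43 and SREBF1, which encodes an SREBP, -0.60 ± 0.19. Of 39 clock genes, 1 fell over all genes and 2 adjusted over the list alone, with a median of -0.29 (camera adjusted p = 9.28e-04). These were tefa, a PAR bZIP factor of the clock output, at -0.56 ± 0.13, and CRY2, a cryptochrome, at -0.48 ± 0.12. CRY1 (ENSDARG00000045768) had -0.31 ± 0.10. Of the 39 clock genes 29 had negative and 10 positive fold changes, so the median does not describe the whole clock. Among the 10 were copies of the activator BMAL1, at 0.37 ± 0.20 (ENSDARG00000006791) and 0.17 ± 0.21 (ENSDARG00000035732), which did not pass. Of 27 lymphocyte genes, 0 fell and 1 rose adjusted over the list alone, nkl.2 at 2.36 ± 0.63 (1.29 without replicate 3 of the 3-year fish), against a list median of -0.27 (camera adjusted p = 0.0147). Levels of nkl.2 were low, 1.24 ± 1.87 CPM (SD) at 3 years and 0.240 ± 0.185 CPM at 1 year. RUNX3 had -0.46 ± 0.20 and the T cell kinase lck -0.41 ± 0.18. The within-run medians were -0.16 and -0.50 for mucous cells and ionocytes, -0.18 and -0.38 for lipid synthesis, -0.32 and -0.21 for the clock, and -0.31 and -0.15 for lymphocytes, low run first. The lymphocyte list was not called without replicate 5 of the 3-year fish (adjusted p = 0.0818).

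The other 19 lists were not called between ages. Among pathways, the median was 0.32 for 13 mitochondrial-genome genes, 0.01 for 29 antioxidant genes, 0.14 for 24 integrated stress genes, 0.24 for 32 glycolysis genes, -0.22 for 27 p53 and senescence genes and -0.19 for 31 inflammatory genes. It was 0.04 for 41 interferon and antigen processing genes, 0.59 for 24 complement genes and 0.03 for 79 cytosolic ribosomal protein genes. Among cell types, the median was 0.01 for 43 keratinocyte genes, -0.11 for 48 dermal fibroblast genes, -0.20 for 24 scale bone genes, 0.14 for 13 melanophore genes and 0.17 for 20 xanthophore and iridophore genes. It was 0.19 for 30 endothelial genes, 0.36 for 14 erythrocyte genes, 0.06 for 24 macrophage genes, 0.09 for 17 neutrophil genes and 0.23 for 22 Schwann cell and nerve genes. Camera's adjusted p ran from 0.0830 to 0.950 over these lists. Some of these medians join opposite values in the low and the high run: -0.84 and 0.43 for interferon and antigen processing (adjusted p of the difference between runs 8.31e-19, camera with its preset correlation), 0.63 and -0.53 for dermal fibroblasts (6.51e-13) and 0.66 and -0.38 for endothelial genes (6.51e-13). The test of these differences between runs was not run with an estimated correlation. In the age comparison that correlation was 0.33, 0.58 and 0.52 for these lists, in that order, against the preset 0.01. These p-values therefore cannot show how firmly the runs differ. Camera's direction between ages was opposite to the median for the antioxidant, interferon, keratinocyte, dermal fibroblast and melanophore lists. Single members that rose were PSAT1, an enzyme of serine synthesis, at 1.47 ± 0.28, the keratin cyt1 at 3.25 ± 0.72, TIMP2 (ENSDARG00000075261) at 1.1 ± 0.26 and the macrophage receptor marco at 0.72 ± 0.16. The cyt1 mean at 3 years was 3.95 ± 4.68 CPM (SD). It rested on replicates 2, 7 and 8 (log2 CPM 3.21, 3.14 and 3.43), with the other 3-year fish at -0.16 or less. Adjusted over the list alone, NFE2L2, which encodes the Nrf2 factor, had -0.43 ± 0.11, NCF1 of the phagocyte oxidase -0.46 ± 0.13 and c1qb 0.43 ± 0.13, and 6 complement genes rose. The complement median was 1.48 in the low run and 0.05 in the high run. In the low run, replicate 4 of the 3-year fish stood apart with a complement list mean of 2.30 (other 3-year fish -0.93 to 0.44). The remaining genes named in advance did not pass: NDUFS1 had 0.68 ± 0.26, MT-ND1 0.66 ± 0.28, SOD2 0.27 ± 0.19, HMOX1 -0.14 ± 0.23, cdkn1a 0.24 ± 0.36, krt4 0.06 ± 0.18, col1a1a -1.06 ± 0.79 and kdrl 0.20 ± 0.27. The PER1 copies had -0.49 ± 0.18 (ENSDARG00000012499) and -0.61 ± 0.32 (ENSDARG00000056885).

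**Figure D1:**
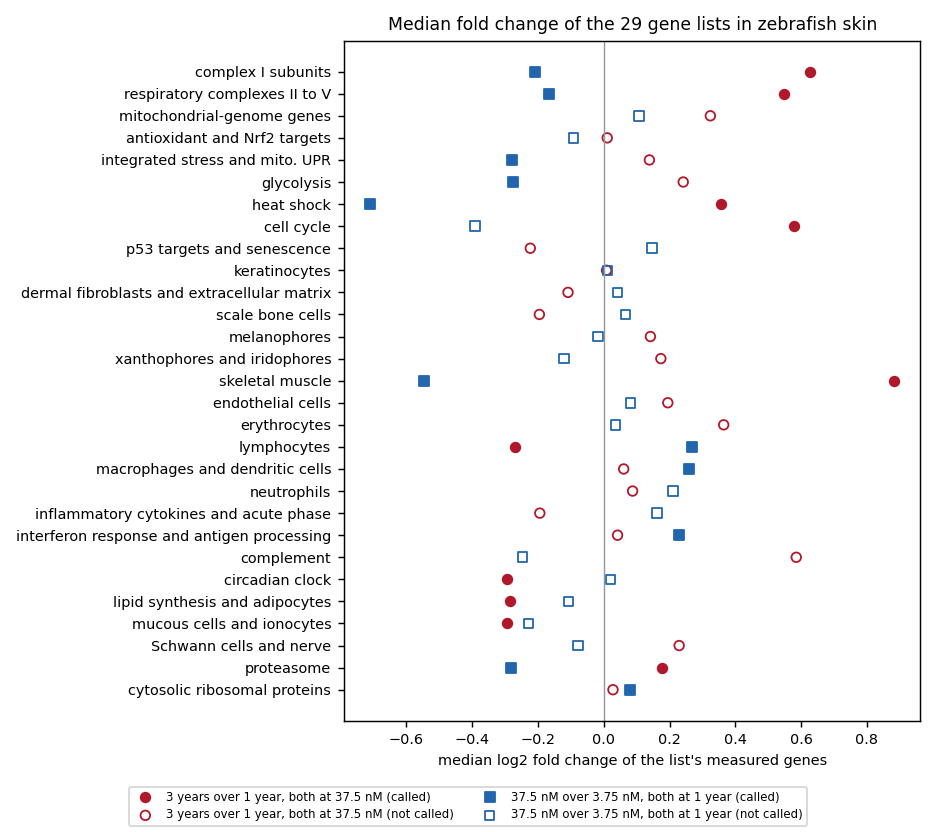
Median log2 fold change of the measured genes of each of 29 lists, for 3 years over 1 year (circles) and 37.5 nM over 3.75 nM (squares), filled where camera with its preset correlation called the list. The heat shock list lay at 0.36 between ages and at -0.71 between concentrations, and the complex I list at 0.63 and -0.21.

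The comparison of 37.5 nM with 3.75 nM, both at 1 year, asks how skin transcripts differ between rotenone concentrations. Heat shock transcripts were lower at the higher concentration (fry adjusted p = 4.00e-04, camera adjusted p = 0.0601 with an estimated correlation), and the clock genes moved both ways. Proteasome transcripts were lower by camera with its preset correlation, but the list was not called with an estimated correlation (adjusted p = 0.640) or by fry (adjusted p = 0.113). hsp90aa1.1 (ENSDARG00000010478), an inducible Hsp90, averaged 12.4 ± 6.28 CPM (SD, n = 9) at 37.5 nM and 45.4 ± 29.9 CPM (n = 9) at 3.75 nM, a log2 fold change of -1.88 ± 0.41 (SE). NR1D1 (ENSDARG00000033160), a repressor of the circadian clock, fell from 10.4 ± 5.89 CPM to 2.37 ± 0.88 CPM, by 2.13 ± 0.34 on the log2 scale. FOXQ1 (ENSDARG00000030896), a forkhead transcription factor, rose from 116.8 ± 74.3 CPM to 408 ± 271 CPM, by 1.8 ± 0.50 on the log2 scale.

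Of 18793 genes tested with edgeR's quasi-likelihood test, 804 changed at a Benjamini-Hochberg adjusted p under 0.05, 240 of them higher and 564 lower at 37.5 nM. Of these, 33 rose and 149 fell by more than 2-fold. After FOXQ1 the largest gains were CYP26C1, a retinoic acid hydroxylase, at 1.54 ± 0.43 (log2 fold change ± SE, n = 9 and 9), TMEM86A at 1.53 ± 0.38, SAMD9L at 1.49 ± 0.39 and SLC25A32 (ENSDARG00000089791), a mitochondrial folate carrier, at 1.46 ± 0.28. bbc3, a p53 target that promotes apoptosis, followed at 1.33 ± 0.33, with the clock-linked nuclear receptor rorcb at 1.32 ± 0.34 and the kinase NUAK2 at 1.31 ± 0.25. The largest losses were cfap70, a ciliary gene, at -4.73 ± 0.80, TDRD9 at -2.86 ± 0.75 and the apolipoprotein apoa1a at -2.85 ± 0.80. Most of the TDRD9 loss came from 1 fish, since without replicate 6 at 3.75 nM it was -1.05 (adjusted p = 0.0480), and cfap70 was -5.38 without replicate 5 at 37.5 nM (adjusted p = 0.0399). The apoa1a values varied widely between fish at 3.75 nM, with log2 CPM of 5.55, 4.98 and 5.28 in replicates 1, 6 and 8. In replicates 4, 5 and 7 they were -0.07, 0.11 and 0.70. SERPINH1 (ENSDARG00000019949), a collagen chaperone, had -2.0 ± 0.55, ODC1, the first enzyme of polyamine synthesis, -1.99 ± 0.49, and pprc1, a coactivator of mitochondrial biogenesis, -1.72 ± 0.33. The adjusted p of the 16 genes lay between 0.0176 and 0.0495, and each moved in its direction in 82.7% or more of the pairs of fish. Both ranges are bounded by the same naming rule as between ages.

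The 3.75 nM fish were deposited in tables of their own, so concentration and table cannot be told apart. The count rests on the low number run: edgeR called 5024 genes there (4 against 4 fish) and 0 in the high run (5 against 5), where 995 genes had an unadjusted p under 0.05 and DESeq2 called 181. The difference itself differed between runs at 1202 genes, among them 322 of the 804. Of 4995 genes called in the low run and measured in both, 71.97% had the same direction in the high run, with a median of 0.10 on the log2 scale there against 0.76 in the low run. Picking genes by the low run favours a larger value there. The 804 genes, called from both runs together, had medians of 1.11 and 0.32 in their direction in the low and high run. Leaving out 1 fish moved the count to between 0 (without replicate 7 at 37.5 nM, where 3885 genes had an unadjusted p under 0.05 in edgeR and DESeq2 called 1327) and 1661 (without replicate 9 at 3.75 nM). For hsp90aa1.1 the within-run values were -2.06 and -1.57, for NR1D1 -2.33 and -1.83, for FOXQ1 1.60 and 2.19 and for cfap70 -6.01 and -4.06, low run first. ODC1 differed by -3.12 in the low run and by -0.25 in the high run (edgeR adjusted p of the difference 0.00854).

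Of 26 heat shock genes, 14 fell over all genes and 18 adjusted over the list alone, and 0 rose, with a median of -0.71. Among them dnajb1b, an Hsp40 co-chaperone, fell by 0.85 ± 0.19 and HSPA4 (ENSDARG00000004754), an Hsp110 relative, by 1.59 ± 0.36, while hsp70l had -0.69 ± 0.29 (edgeR adjusted p = 0.158). Camera called the list (adjusted p = 5.89e-11, and adjusted p = 0.0601 with an estimated correlation). Fry called it down (adjusted p = 4.00e-04). The list mean differed by -0.718 (exact permutation p = 8.23e-05, two-sided, 0.00173 adjusted over 42 comparisons of list means). It differed by -1.11 in the low run (exact permutation p = 0.0286, the smallest that 4 against 4 fish allow) and by -0.408 in the high run (exact permutation p = 0.0159), each 0.116 after adjustment. These differences differed between runs by -0.697 (exact permutation p = 0.00183, 0.0128 adjusted over 7 measures).

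**Figure D2:**
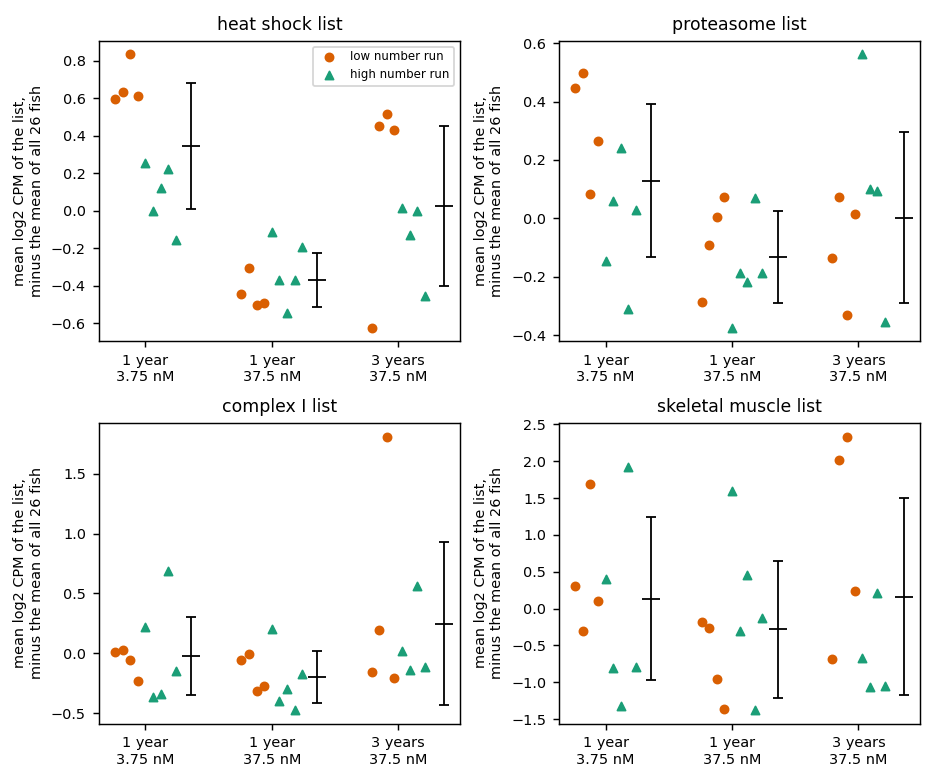
Mean log2 CPM per fish of the heat shock, proteasome, complex I and skeletal muscle lists, minus the mean of all 26 fish, with circles for the low and triangles for the high number run and bars for the group mean ± SD. The heat shock mean was 0.347 ± 0.335 at 3.75 nM and -0.371 ± 0.145 at 37.5 nM in 1-year fish, and replicate 3 of the 3-year fish stood at 1.81 in the complex I list.

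Of 39 proteasome genes, 5 fell over all genes and 19 adjusted over the list alone, with a median of -0.28 (camera adjusted p = 1.30e-10, and adjusted p = 0.640 with an estimated correlation). PSMD11 (ENSDARG00000005134) and PSMD12, both of the regulatory particle, fell by 0.59 ± 0.13 and 0.54 ± 0.13, and PSMB7 of the catalytic core by 0.61 ± 0.14. Of 24 integrated stress and mitochondrial unfolded protein response genes, 4 fell over all genes and 6 adjusted over the list alone, with a median of -0.28 (camera adjusted p = 0.00722, and adjusted p = 0.640 with an estimated correlation). The mitochondrial protease LONP1 fell by 1.07 ± 0.24, and the mitochondrial chaperones HSPD1 and HSPA9 fell by 1.35 ± 0.36 and 0.71 ± 0.19. Of 32 glycolysis genes, 1 fell over all genes and 1 adjusted over the list alone, with a median of -0.28 (camera adjusted p = 0.00722, and adjusted p = 0.640 with an estimated correlation). That gene was pgam1a, at -0.68 ± 0.15, while ldhbb had -2.79 ± 0.87 and HK1, a hexokinase, -0.61 ± 0.21. At 3.75 nM ldhbb was highest in the same fish as apoa1a, replicates 1, 6 and 8 (log2 CPM 4.48, 4.08 and 4.42). What these fish share was not tested. The medians in the low and high run were -0.42 and -0.16 for the proteasome, -0.63 and -0.08 for integrated stress, and -0.31 and -0.17 for glycolysis.

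Of 40 measured genes of the complex I list, 0 passed over all genes and 0 adjusted over the list alone (edgeR, with 4311 of all genes at an unadjusted p under 0.05), and the median was -0.21. Camera called the list (adjusted p = 1.40e-04, and adjusted p = 0.877 with an estimated correlation). The list mean differed by -0.177 (exact permutation p = 0.195, 0.356 adjusted over 42 comparisons of list means), and by -0.095 with the muscle list mean as a term (permutation p = 0.324), so a difference between concentrations was not resolved. ndufab1b had -0.40 ± 0.16, ndufc1 -0.26 ± 0.11 and NDUFAB1 -0.24 ± 0.11. The 45 genes of the list for complexes II to V had a median of -0.17 with 0 passing in either count (camera adjusted p = 0.00200, and adjusted p = 0.877 with an estimated correlation), among them cycsb, a cytochrome c and so an electron carrier listed with the subunits, at -0.55 ± 0.17, COX7A2 at -0.34 ± 0.10 and ATP5MC3 at -0.34 ± 0.12. Of 28 skeletal muscle genes 0 passed, and the median was -0.55 (camera adjusted p = 0.0301, and adjusted p = 0.877 with an estimated correlation), with ACTA1 copies at -1.37 ± 0.72 (ENSDARG00000055618) and -0.82 ± 0.47 (ENSDARG00000036371) and pvalb1 at -1.62 ± 0.90. Without replicate 8 at 3.75 nM the former ACTA1 copy (ENSDARG00000055618) was at -0.38, and pvalb1 was at -0.60 without replicate 3 at 3.75 nM and at -2.30 without replicate 5 at 37.5 nM. The medians in the low and high run were -0.11 and -0.29 for complex I, -0.01 and -0.26 for complexes II to V, and -1.24 and -0.13 for muscle. The call for complexes II to V was lost without replicate 8 of the 3.75 nM fish (adjusted p = 0.125).

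The macrophage, lymphocyte and interferon lists lay higher at 37.5 nM by camera with its preset correlation, while the neutrophil, inflammatory and complement lists were not called. All 24 macrophage and dendritic cell genes had positive fold changes and 0 passed in either count, with a median of 0.26 (camera adjusted p = 1.35e-04, and adjusted p = 0.640 with an estimated correlation). The receptor gene csf1ra had 0.59 ± 0.20, marco 0.38 ± 0.13 and LCP1 0.30 ± 0.12. Of 26 lymphocyte genes 1 rose over all genes and 1 adjusted over the list alone, with a median of 0.27 (camera adjusted p = 0.00200, and adjusted p = 0.640 with an estimated correlation). That gene was RUNX3, a T cell transcription factor, at 0.80 ± 0.20, while lck had 0.45 ± 0.16 and the homing receptor CCR7 0.45 ± 0.17. Of 41 interferon response and antigen processing genes, 1 rose and 1 fell over all genes, and 3 rose and 1 fell adjusted over the list alone, with a median of 0.23 (camera adjusted p = 6.34e-04, and adjusted p = 0.877 with an estimated correlation). stat2, which transmits the interferon signal, rose by 0.72 ± 0.16 and isg20 fell by 0.68 ± 0.13, while helz2a had 0.71 ± 0.20. Of 79 cytosolic ribosomal protein genes 0 passed, and the median was 0.08 (camera adjusted p = 0.00722, and adjusted p = 0.877 with an estimated correlation), with RPL6 at 0.15 ± 0.11, RPS10 at 0.13 ± 0.11 and RPS7 at 0.13 ± 0.11. The medians in the low and high run were 0.31 and 0.16 for macrophages, 0.41 and 0.13 for lymphocytes, 0.44 and 0.07 for interferon, and 0.14 and 0.03 for ribosomal proteins.

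The 39 circadian clock genes moved in both directions. Over all genes 6 rose and 5 fell, and adjusted over the list alone 10 rose and 9 fell, with a median of 0.02 (camera adjusted p = 0.559). Fry's test of change in either direction gave an adjusted p = 2.51e-09. That test passed other lists as well, such as heat shock (adjusted p = 1.48e-05) and p53 targets and senescence (adjusted p = 0.0156). A PER1 copy (ENSDARG00000012499), a core repressor of the clock, fell by 1.5 ± 0.22 in all pairs of fish, with NR1D1 and dbpa, which fell by 1.41 ± 0.22. The activator BMAL1 (ENSDARG00000035732) rose by 0.89 ± 0.18, rorcb by 1.32 ± 0.34 and nfil3-5 by 1.14 ± 0.27. The within-run values of that PER1 copy were -1.52 and -1.47. The further PER1 copy (ENSDARG00000056885) had -0.94 ± 0.28 (edgeR adjusted p = 0.0602).

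The other 17 lists were not called between concentrations. Among pathways, the median was 0.11 for 13 mitochondrial-genome genes, -0.09 for 29 antioxidant genes, -0.39 for 42 cell cycle genes, 0.15 for 27 p53 and senescence genes, 0.16 for 32 inflammatory genes, -0.25 for 25 complement genes and -0.11 for 38 lipid genes. Among cell types, the median was 0.01 for 43 keratinocyte genes, 0.04 for 48 dermal fibroblast genes, 0.07 for 24 scale bone genes, -0.02 for 13 melanophore genes and -0.12 for 20 xanthophore and iridophore genes. It was 0.08 for 30 endothelial genes, 0.04 for 14 erythrocyte genes, 0.21 for 17 neutrophil genes, -0.23 for 22 mucous cell and ionocyte genes and -0.08 for 22 Schwann cell and nerve genes. Camera's adjusted p ran from 0.0590 to 0.929 over these lists, and its direction was opposite to the median for the keratinocyte, dermal fibroblast, melanophore and erythrocyte lists. Some medians were opposite in the low and the high run, such as those for keratinocytes (-0.28 and 0.19, adjusted p of the difference between runs 7.17e-06, camera with its preset correlation), mitochondrial-genome genes (0.52 and -0.14, 0.00209), mucous cells and ionocytes (-0.59 and 0.27, 0.00693) and dermal fibroblasts (-0.35 and 0.15, 0.0209). The test of these differences between runs was not run with an estimated correlation, so its p-values cannot show how firmly the runs differ. In the cell cycle list 5 genes fell over all genes, and 1 rose and 10 fell adjusted over the list alone, with MCM3 at -1.05 ± 0.22. In the complement list 2 genes fell over all genes and 8 adjusted over the list alone. At 3.75 nM its member cfh was highest in replicates 1, 6 and 8 (log2 CPM 2.47, 2.26 and 2.35), as was apoa1a. Single members that changed were TXNRD3, a thioredoxin reductase, at -0.55 ± 0.14, krt18a.1 at -0.57 ± 0.14, BMP2 (ENSDARG00000041430) at 0.54 ± 0.13, ABCB9 at 0.57 ± 0.15 and cfh, a complement regulator, at -2.06 ± 0.46, while KIT had 0.50 ± 0.15 and passed over the list alone. The remaining genes named in advance did not pass: NDUFS1 had -0.23 ± 0.15, MT-ND1 -0.14 ± 0.19, SOD2 -0.03 ± 0.11, HMOX1 0.45 ± 0.19, mki67 0.29 ± 0.42 (0.91 without replicate 6 at 3.75 nM), PCNA -0.60 ± 0.21, cdkn1a 0.24 ± 0.34, krt4 -0.27 ± 0.26, col1a1a 0.15 ± 0.73 and kdrl -0.11 ± 0.19.

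**Figure D3:**
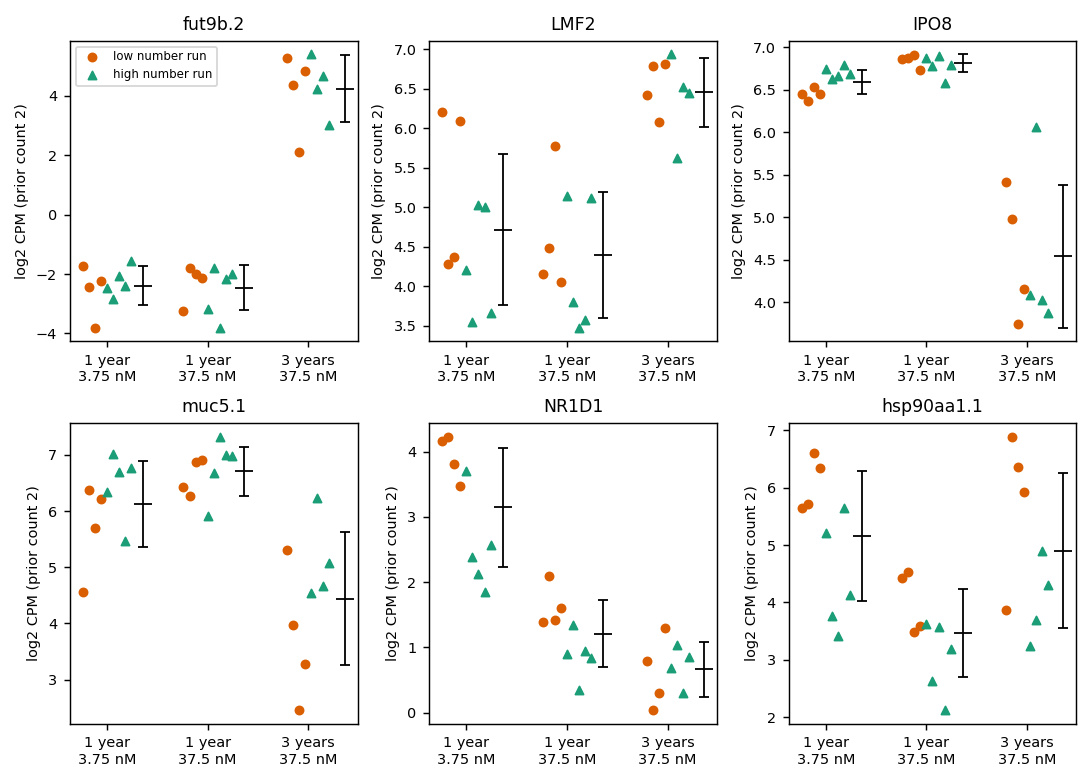
Log2 CPM per fish of fut9b.2, LMF2, IPO8, muc5.1, NR1D1 and hsp90aa1.1, with circles for the low and triangles for the high number run and bars for the group mean ± SD. IPO8 lay lower in each of the 8 fish aged 3 years than in any of the 18 fish aged 1 year, and NR1D1 fell by 2.13 from 3.75 nM to 37.5 nM.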

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

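The tests of list means and of differences between number runs, muscle, 1 fish left out of the complex I list, hour of sampling, strain variants, shared reads, other splits of the fish, genes detected and median correlation were chosen after the patterns were seen, although the outcomes of the muscle tests and of the test without 1 fish were not known when these were set. The gene counts within a number run and with number run as a term were fixed in advance. Of 34 list means and library measures, each tested in 3 groups, 12 tests found a fish set apart from the others, and chance alone sets one apart in about 1 in 20 groups.

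Replicate 3 of the 3-year fish stood apart in 7 measures. Its TMM factor was 0.775, against 0.985 to 1.12 in the other 3-year fish. Its 10 most abundant genes took 20.04% of the counts, against 14.2% to 16.4%. Its median correlation with the other fish was 0.907, against 0.935 to 0.951. Relative to the mean of all fish, its list mean was 1.81 for complex I (others -0.21 to 0.57), 1.67 for complexes II to V (-0.20 to 0.49), 1.09 for glycolysis (-0.39 to 0.21) and 1.22 for Schwann cells and nerve (-0.28 to 0.11). Replicate 4 of the 3-year fish had 0.840 for neutrophils (others -0.14 to 0.29) and 2.30 for complement (-0.93 to 0.44). Replicate 8 of the 3.75 nM fish had 0.561 for endothelial cells (others -0.41 to 0.07). Replicate 6 of the 3.75 nM fish had 25349 genes detected (others 23302 to 24224) and a median correlation of 0.899 (others 0.928 to 0.953). In the dose comparison, the difference between concentrations differed between number runs at 1202 genes by edgeR's interaction term.

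Heat shock transcripts were lower at 37.5 nM than at 3.75 nM in 1-year fish. Both groups hold 4 fish of the low and 5 of the high run, so a shift between runs alone cannot give the difference, but its size differed between runs (-1.11 and -0.408). Skeletal muscle in the samples is argued against, since with the muscle list mean as a term the difference was -0.665 ± 0.111 (SE) with a permutation p of 0.000247. The hour of sampling may contribute and stays open: the clock index, built after the clock genes were seen to move both ways, was higher at 37.5 nM by 1.58 in the low and 1.17 in the high run, and a difference between the runs was not resolved (exact permutation p = 0.338). Rotenone concentration and the separate deposition of the 3.75 nM fish go together in all fish and cannot be told apart.

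The complex I list lay higher in the 3-year fish by camera with its preset correlation. Its list mean did not pass after adjustment (exact permutation p = 0.0359, 0.116 adjusted over 42 comparisons of list means). Replicate 3 of the 3-year fish could account for much of this: without it the difference of the list mean fell from 0.445 to 0.221 (exact permutation p = 0.0893). Camera with its preset correlation called the list without that fish (adjusted p = 2.33e-06), and with an estimated correlation it called no age list even with all fish (0.801 for complex I). Muscle in the samples stays open, since with the muscle list mean as a term the difference was 0.310 ± 0.179 (SE, permutation p = 0.0956), and with the fish high in muscle left out it was 0.243 (exact permutation p = 0.0433). Age and strain, which go together, stay open as biological explanations and were not tested apart.

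Values of 21 genes showed no overlap between the 3-year fish and all 18 others, 8 higher and 13 lower, against at most 2 genes in 99 random splits (mean 0.0303). The gap was over 2-fold for 4 of the 21. A variant of the strain may underlie these, but age and strain label go together, so the 21 genes cannot be told apart as effects of either. Reads moved to fut9b.2 and fut9b.3 from the counts of the other 4 copies stay open. Together fut9b.2 and fut9b.3 gained 32.0 CPM. The other 4 copies did not fall by as much but differed by 14.8 CPM (SE 16.9, exact permutation p = 0.376 against no difference). That value lay 2.78 standard errors above such a fall, but this standard error leaves out the spread of the gain. Moved reads would leave the sum of the 6 copies unchanged. That sum was 139.6 ± 59.4 CPM (SD) at 3 years and 92.7 ± 20.5 CPM at 1 year and 37.5 nM. A difference of the sum was not resolved (exact permutation p = 0.144 on the log2 scale). Reads that were counted for no copy in the 1-year fish are not covered by these tests and stay open as well, since the similarity of the copies was not analysed.

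Random splits of the same fish argue against chance as the source of both counts of changed genes, as far as 100 splits can show. Between ages the real split gave 241 genes and the highest other of 100 splits 1, and between concentrations the real split gave 804 and the highest other 14, so in each case 1 split, the real one, gave as many, a share of 0.01 and the smallest that 100 splits allow. Among 100 splits that kept the numbers of low-run and high-run fish per group, the highest other gave 15 genes between ages and 89 between concentrations. With the number run as a term the real splits gave 354 and 1427 and the highest others 39 and 257. This does not bear on the high run alone, where edgeR called 0 genes between concentrations (995 at an unadjusted p under 0.05, and 181 by DESeq2).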

How the results depend on the processing

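The muscle term, the omission of fish high in muscle and the list tests within number runs were chosen after seeing the data, and all other settings before. No paired analysis was possible because replicate numbers only follow the order of deposition. With edgeR, the age count of 241 ranged from 169 to 354 under RLE, library size alone, both other count filters, all 26 fish, the number run term and the muscle term. It was 1267 with DESeq2, 85 and 71 with limma-trend on RPKM plus 0.1 and plus 1, 34 and 19 in the low and high run alone, 26 with glmTreat and 75 without fish high in muscle. The dose count of 804 ranged from 626 to 1041 under RLE, library size alone, 10 counts in 8 fish and all 26 fish. It was 209 without a count filter, 1851 with DESeq2, 3 and 0 with limma-trend on RPKM plus 0.1 and plus 1, 1427 with the number run term, 5024 and 0 in the low and high run alone, 0 with glmTreat, 401 with the muscle term and 252 without fish high in muscle. Counts of 0 stood beside genes at an unadjusted p under 0.05: 3328 with limma (RPKM plus 1), 702 with glmTreat and 995 in the high run, where DESeq2 called 181. Leaving out 1 fish at a time gave 64 (1 year, 37.5 nM, replicate 8) to 712 (3 years, replicate 6) age genes, and every omission except 3 years replicate 3 moved the count over 1.5 times. It gave 0 (37.5 nM replicate 7) to 1661 (3.75 nM replicate 9) dose genes, and every omission except 37.5 nM replicates 6, 8 and 9 and 3.75 nM replicates 5 and 6 moved the count over 1.5 times. Without 37.5 nM replicate 7, edgeR left 3885 genes at an unadjusted p under 0.05 and DESeq2 called 1327. The cause of each changed count was not tested.

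Camera called 10 age lists and 11 dose lists, and 9 to 13 in either comparison with 1 fish left out. With the number run as a term it called 10 age lists and 10 dose lists. With an estimated correlation it called 0 and 0 (unadjusted p under 0.05 for 0 age and 1 dose list). Fry called 0 age lists (3 at an unadjusted p under 0.05) and 1 dose list, heat shock. Fry's test of change in either direction passed further lists in both comparisons. Between ages these included mucous cells and ionocytes (adjusted p = 0.00107) and macrophages (adjusted p = 0.00284), and between concentrations the proteasome (adjusted p = 0.0258). The direction of camera reversed in the high run for the age lists of dermal fibroblasts (adjusted p = 4.03e-06), skeletal muscle (0.0174), endothelial cells (8.54e-05), interferon (1.94e-07) and ribosomal proteins (0.0174), and for the dose lists of keratinocytes (2.30e-05), dermal fibroblasts (0.0152) and skeletal muscle (0.372). It reversed for the age proteasome list in the low run (0.858) and for the age ribosomal list without fish high in muscle (0.0269). The cause was not tested. Skeletal muscle lost its call in 5 of the age and 6 of the dose omissions (highest adjusted p 0.421 and 0.404) and ribosomal proteins in 6 dose omissions (highest 0.598). Of 25 named genes called between ages, 18 lost the call in at least 1 omission, and of 35 between concentrations all 35 did. With the number run as a term, 3 lost it between ages and 1 between concentrations. No named gene called over all genes changed sign in any setting, while 6 of 36 uncalled ones between ages (myhz2, 1 ACTA1 copy, HMOX1, krt4, col1a1a and kdrl) and 7 of 33 between concentrations (pvalb1, MT-ND1, SOD2, cdkn1a, krt4, col1a1a and kdrl) did in at least 1.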

Other observations

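The clock index, the comparison between number runs and the overlap of the age and dose comparisons were chosen after the results were seen. Clock genes moved in opposite directions between rotenone concentrations. The index was built after these moves were seen, so it restates them and is no separate evidence. It is the mean of 10 activator-side genes minus that of 11 repressor and output genes, and was 0.228 ± 0.497 (SD, n = 9) at 37.5 nM and -1.13 ± 0.37 (n = 9) at 3.75 nM (log2 scale), a difference of 1.35, with 1.58 in the low run and 1.17 in the high run. Among single genes, hlfa rose by 0.69 ± 0.13 (SE), the cryptochrome genes cry3a by 0.60 ± 0.09 and cry3b by 0.90 ± 0.23, while dbpb fell by 0.63 ± 0.12 and NR1D2 by 0.70 ± 0.17. Between ages the index was 0.782 higher at 3 years (exact permutation p = 0.0306, 0.116 after adjustment), with 0.925 in the low run and 0.571 in the high run.

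Skin of fish in the high number run differed from that in the low run in both 1-year groups. With group as a term, edgeR called 2801 of 18951 genes, 1440 higher and 1361 lower in the high run. Within groups it called 1513 genes at 1 year and 37.5 nM and 1581 at 3.75 nM, and 0 at 3 years, where 2204 had an unadjusted p under 0.05 and DESeq2 called 473. Among single genes chosen after their values were seen, the sodium pump subunit atp1a1a.2 was lower in the high run at -3.69 ± 0.47 (SE) and the cotransporter slc12a10.2 at -3.70 ± 0.50, as were the keratin krt17 at -1.56 ± 0.20, CYP27C1 at -1.53 ± 0.17 and CRTAC1 at -1.27 ± 0.12. The amino acid transporter SLC38A4 was higher at 2.11 ± 0.28, with AMD1 of polyamine synthesis at 1.36 ± 0.21 and the Wnt effector LEF1 at 1.31 ± 0.19. By camera, dermal fibroblast and matrix genes (median 0.53, adjusted p = 1.72e-10), scale bone genes (0.42, 6.04e-04) and cell cycle genes (0.82, 0.00383) were higher, and ribosomal protein genes (-0.30, 6.01e-28) and glycolysis genes (-0.32, 0.00140) lower. Also called were lipid synthesis (0.37, 0.0218) and p53 (0.20, 0.0493), which were higher, and heat shock (-0.24, 0.0112), complexes II to V (-0.16, 0.0299), skeletal muscle (-0.37, 0.0493), the proteasome (-0.07, 0.0493), antioxidant genes (-0.09, 0.0493) and mucous cells and ionocytes (-0.24, 0.0493), which were lower. None of these calls held with an estimated correlation (adjusted p of 0.731 or more).

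Both comparisons share the 1-year fish at 37.5 nM, so their fold changes are linked by construction. Across 18641 genes, which are not independent replicates, they correlated at r = -0.396, against -0.507 to -0.472 in 20 simulations with no change. Their covariance was -0.0955, beyond the -0.0512 to -0.0459 of the simulations, and with separate fish of the shared group for each comparison r was -0.323 and -0.181. The simulations drew each gene independently and held no differences in number run or muscle, so they cannot test a link. Of the genes called, 7 were higher at 3 years and lower at 37.5 nM, 2 were lower and then higher, 0 were higher in both and 1 was lower in both. The shared fish favour opposite signs, so these counts say nothing on their own about a link.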
